A study of Mus musculus with 32 samples.

How the data were processed

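RNA of 32 mouse hearts was measured by sequencing of polyA RNA. Per the labels, RNA was isolated with a column kit, stranded mRNA libraries were prepared and sequenced on an Illumina instrument, and reads were assigned to the GRCm38 build. The deposited table holds raw read counts, whole numbers for 46078 Ensembl gene identifiers in 32 libraries, with no normalization by the authors. The aligner, the counting program and its handling of strand and of reads shared between genes are not given in the sources used here. Columns were matched to labels by the sample names both carry, with no column left over. Of the identifiers, 45229 were in GENCODE release M21 (GRCm38), which gave symbols, positions and gene types.

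Each library was assigned to 1 of 8 groups by labelled genotype and labelled age, with 4 libraries per group. Comparisons within an age used the 16 libraries of that age and comparisons between ages used all 32. In each, genes were filtered by filterByExpr over the groups, scaled by TMM factors and tested with edgeR's quasi-likelihood test after robust dispersion estimation, with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. A change is the fitted log2 fold change. Its SE is its size divided by the square root of the F statistic and is approximate at low counts. The comparisons were Dars2 KO against WT, DKO against Dars2 KO, Chop KO against WT, DKO against Chop KO and the interaction of both losses at each age, the difference of the first and of the following comparison between ages, and WT between ages. Labelled age and project code of the sample names coincide and cannot be told apart.

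Before the data were examined, 39 gene lists were fixed, covering the integrated stress response, amino acid, folate and energy metabolism, mitochondrial gene expression, protein quality control, cardiac stress, the sarcomere, the cell cycle and markers of other cell types that heart tissue may hold. The lists overlap in members (Mthfd2 and Asns stand in more than 1), so their counts are not independent. Each list with at least 3 measured members was tested against all other genes by camera on limma-voom values with the preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Counts of changed members are given over all genes tested and, with p adjusted over the list alone, beside it. Genes were named by a rule fixed at the same time. It took Dars2 and Ddit3 and, among called genes of at least 1 CPM in the higher group whose libraries did not overlap between the groups, the 8 largest changes each way for Dars2 KO against WT and DKO against Dars2 KO, and 4 each way for the other comparisons. It took up to 3 members of each list with the smallest p. No condition on overlap applied to interactions and age comparisons, Xist and Y-linked genes were left out, and some names were left out for length. Overlaps of called genes between comparisons were tested with a hypergeometric test; the pairs of comparisons at both ages that share genotypes were added after the data were seen.

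A ratio against a group of 1 to 3 counts is given with an exact (Clopper-Pearson) 95% interval, and a group at 0 counts is given a floor of 3 counts over the group. Reads carry no molecular identifiers here, so intervals and floors cover counting error only. Within groups, 48 pairs of libraries varied by 7.59 to 113 times the counting variance, a mean over genes in which abundant genes weigh most. The pipeline was tested on simulated counts with known changes (16119 genes labelled 1 week). For Dars2 KO against WT labelled 1 week, edgeR recovered 53.7%, 82.1% and 98.5% of true 1.5-fold, 2-fold and 4-fold changes, with 3.11% false calls. At the 2 weeks label (17062 genes) these were 79.1%, 98.5% and 100%, with 4.64% false calls. For the interaction they were 23.9%, 61.2% and 93.9% at the 1 week label (1.65% false) and 50.7%, 88.1% and 98.5% at the 2 weeks label (4.24% false). The simulated counts were drawn independently for each gene, without differences that libraries of 1 group share over many genes. These shares therefore do not tell what the tests could recover in the real groups, nor what a count of 0 called genes excludes. Camera called the list that was shifted in simulated data and 0 of 33 lists that share no member with it. Members of a list were uncorrelated in the simulated counts, so this could not test the preset correlation. In the data the estimated correlation was 0.674 for the cytosolic ribosome labelled 1 week and 0.806 for the cell cycle list labelled 2 weeks.

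Sex was read from Xist and from the sum of Ddx3y, Uty, Kdm5d and Eif2s3y. Alternatives were DESeq2 and limma-voom in place of edgeR, RLE in place of TMM factors, no filter and a filter of at least 1 CPM in at least 4 libraries, the labelled sex as a covariate, the replicate number as a block, a fit of the compared groups alone, and each library left out in turn. Sex read from the transcripts as a covariate was added after the data were seen. The split that called most genes for Dars2 KO against WT labelled 2 weeks was compared with the age differences of WT and, after that result was seen, of Chop KO. Splits of the same libraries into groups of the same size counted how often as many genes were called. Replicate numbers did not pair libraries: at each age 8 of 24 correlations between libraries of the same number exceeded 0.1 after the group means were removed, and the library of the same number was the best match in 7 of 24 cases labelled 1 week and 4 of 24 labelled 2 weeks. Proteomic data named in the series title were not among the files. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.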

Results

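Gene-level read counts were compared for 32 mouse hearts, each from its own animal, sequenced as stranded polyA libraries. The labels give 4 genotypes at 2 ages, 1 week and 2 weeks, with 4 libraries in each of the 8 groups. Dars2 KO mice lack Dars2, the mitochondrial aspartyl-tRNA synthetase, in heart and skeletal muscle, through a Cre recombinase driven by the muscle creatine kinase promoter. Chop KO mice lack Chop, a transcription factor of the integrated stress response that is encoded by Ddit3. DKO mice carry both changes and WT mice carry no Cre. Per the series design, the ages stand for early and late stages of mitochondrial dysfunction. The comparisons therefore ask what loss of Dars2 did to the heart transcriptome at each age, and how loss of Chop altered it. Library totals ran from 32061479 to 45146926 counts. Transcripts of the mitochondrial genome took 20.4% to 26.6% of the counts in the libraries labelled 1 week and 12.1% to 15.9% in those labelled 2 weeks.

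The deleted genes and the sex of each animal were checked against the labels. Dars2 (ENSMUSG00000026709, GRCm38 chromosome 1, 161040601 to 161070658) stood at 14.7 ± 1.37 counts-per-million (CPM; mean ± SD, n = 4) in WT labelled 1 week, 2.13 ± 0.412 in Dars2 KO and 1.97 ± 0.394 in DKO. The values labelled 2 weeks were 13.8 ± 2.22 CPM in WT, 5.84 ± 0.58 in Dars2 KO and 3.27 ± 0.693 in DKO. At each age every Dars2 KO and DKO library lay below every WT library. Chop KO libraries, whose Dars2 alleles carry no Cre by the labels, stood lower and more spread than WT, at 7.99 ± 5.05 and 8.03 ± 3.48 CPM. Their difference from WT did not pass the edgeR test at either age (-0.84 log2, adjusted p = 0.298, and -0.81 log2, adjusted p = 0.143). It passed at the 1 week label without Chop KO replicate 2 (adjusted p = 0.0292). At the 2 weeks label Dars2 passed with DESeq2 (adjusted p = 0.021) and without Chop KO replicate 1 (adjusted p = 0.0062). Ddit3 (ENSMUSG00000025408, GRCm38 chromosome 10, 127290774 to 127296288) still gave 20 ± 1.05 CPM in Chop KO labelled 1 week and 17.5 ± 2.88 CPM in Chop KO labelled 2 weeks. WT stood at 18.3 ± 3.3 and 24.4 ± 2.4 CPM, so a gene-level count did not separate Chop KO from WT. DKO labelled 1 week lay at 17.09 to 23.86 CPM, below Dars2 KO at 27.07 to 39.47 CPM. Labelled 2 weeks these groups overlapped, at 16.45 to 26.16 CPM and 17.44 to 29.04 CPM. Which part of the gene the allele lacks is not given in the labels.

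**Figure D1:**
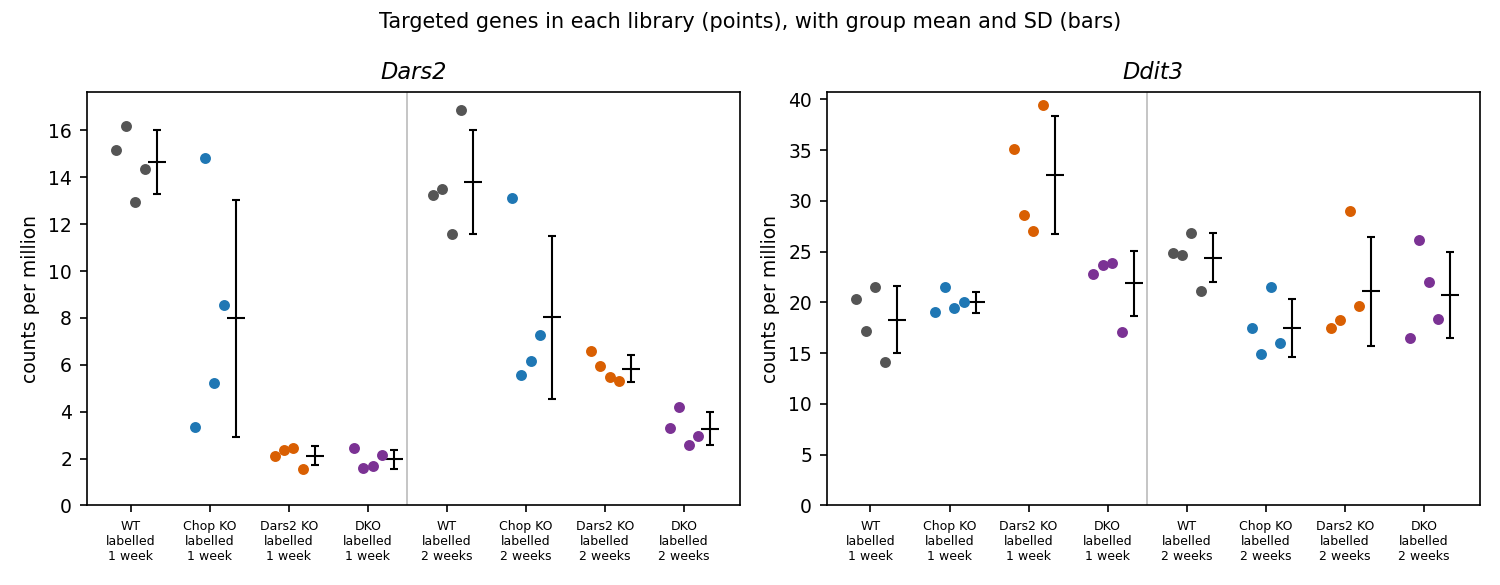
Levels in CPM of Dars2 and Ddit3 in each of the 32 libraries by labelled age and genotype; points are libraries and bars the mean with SD of 4 libraries. Dars2 averaged 14.7 CPM in WT and 2.13 CPM in Dars2 KO labelled 1 week, while Ddit3 averaged 20 CPM in Chop KO labelled 1 week.

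Xist, the transcript that silences an X chromosome in females, and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y parted the libraries without overlap. Female libraries had at least 189 CPM of Xist and at most 0.289 CPM of the Y-linked genes together. Male libraries had at most 0.878 CPM of Xist and at least 100.5 CPM of the Y-linked genes. The sex so read matched the label of the library itself in 10 of 32 libraries. It matched the label of the same genotype and replicate number at the other age in 32 of 32. Ages are therefore written as labelled throughout, and their order is taken up in the closing section.

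**Figure D2:**
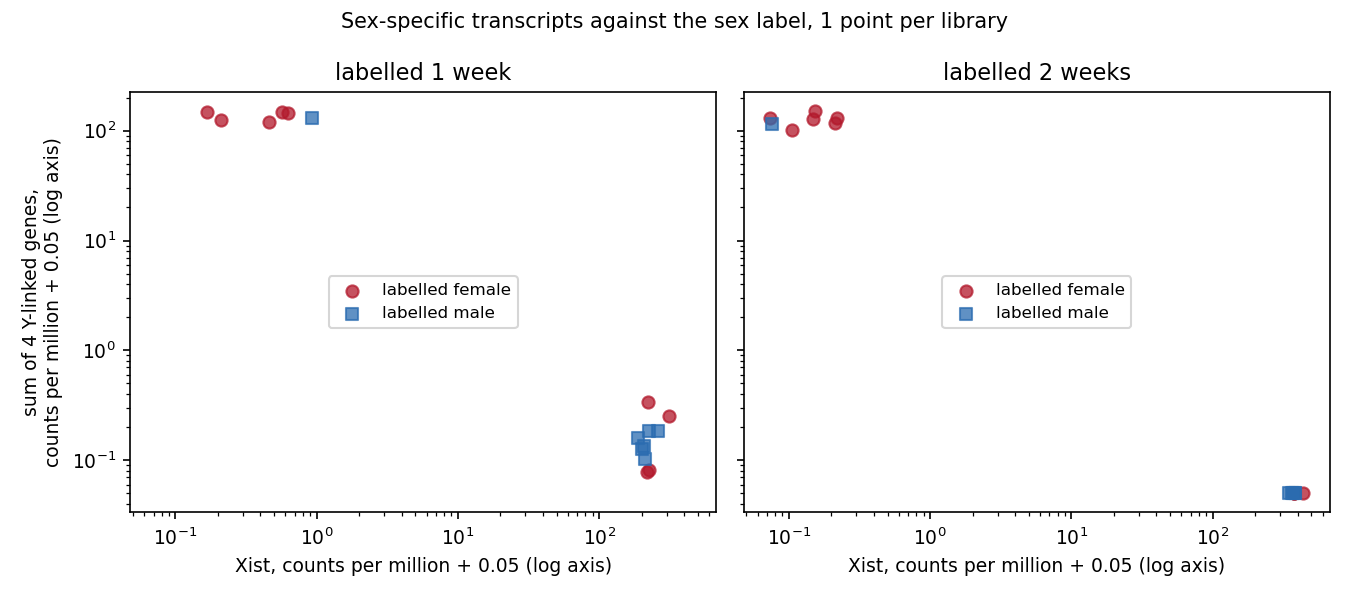
Xist (x axis) against the sum of 4 Y-linked transcripts (y axis), both in CPM plus 0.05 on log axes, 1 point per library, in a panel for each labelled age, with circles for libraries labelled female and squares for those labelled male. In each panel labels of both kinds fall in both clusters, and the own label matched the transcripts in 10 of 32 libraries.

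The genes that rose most in Dars2 KO hearts labelled 1 week included those of single hormones and of enzymes of asparagine and folate metabolism. Fgf21, a hormone of energy balance, rose by 6.21 ± 0.93 on the log2 scale (± SE of the fitted change, 4 libraries per group, as for every such value here; GRCm38 chromosome 7, 45613886 to 45615490). Gdf15, a cytokine secreted under cell stress (GRCm38 chromosome 8, 70629393 to 70632456), rose by 4.63 ± 0.55, from 0.864 ± 0.174 to 21.6 ± 8.42 CPM. Adm2, a peptide hormone, went from 3 counts over the WT group to 143, a ratio of 50 with a 95% counting interval of 16.8 to 245. Mthfd2, a mitochondrial enzyme of folate metabolism (GRCm38 chromosome 6, 83305691 to 83325908), rose by 4.88 ± 0.24. Asns, the asparagine synthetase (GRCm38 chromosome 6, 7675169 to 7693254), rose by 4.22 ± 0.26, from 2.31 ± 0.273 to 43.4 ± 18.4 CPM. Soat2, which esterifies cholesterol, rose by 4.57 ± 0.31, and the transcription factor Tfcp2l1 by 3.80 ± 0.30. Vmn2r3, a gene of the vomeronasal receptor family, went from 0 counts in the WT group to 952, at least 333-fold against a floor of 3 counts over the group. Adjusted p from edgeR lay between 1.55e-08 for Mthfd2 and 0.00324 for Fgf21. Of 9 growth factor and hormone genes of the fixed list, 2 rose (2 adjusted over the list alone), with 0 called by limma-voom (camera adjusted p = 0.0575, adjusted p = 0.576 with an estimated correlation).

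In all, 125 of 16324 genes passed edgeR's test in this comparison, 106 higher and 19 lower in Dars2 KO. Of 35 targets of the integrated stress response and its transcription factor ATF4, 20 rose (25 adjusted over the list alone), with a median of 0.748 over the list. Among them were Atf5, a transcription factor of that response (1.94 ± 0.11), and Slc7a5, a transporter of large neutral amino acids (2.66 ± 0.17). The test of the list against all other genes with camera gave adjusted p = 1.5e-39, and adjusted p = 0.000732 with an estimated correlation. Of 18 genes of serine, glycine and folate metabolism, 5 rose (6 adjusted over the list alone). They included Phgdh, the enzyme that opens serine synthesis (3.62 ± 0.24), and Aldh1l2, a mitochondrial enzyme of folate metabolism (1.21 ± 0.16); camera adjusted p = 1.2e-06, adjusted p = 0.0159 with an estimated correlation. Of 12 genes of proline and glutamate synthesis, 3 rose and 0 fell (3 and 2 adjusted over the list alone): Asns, Aldh18a1 (1.48 ± 0.13) and Pycr1 (2.03 ± 0.21), the latter a pair of enzymes of the proline route (camera adjusted p = 0.0153, adjusted p = 0.386 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 10 rose (13 adjusted over the list alone), among them Mars (0.67 ± 0.07), Sars (1.05 ± 0.11) and Yars (0.69 ± 0.08; camera adjusted p = 1.02e-24, adjusted p = 0.0702 with an estimated correlation). Ddit3 itself rose by 0.82 ± 0.15 (adjusted p = 0.00843).

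Other groups of the same comparison held few called genes, and no list of this paragraph kept a camera call with an estimated correlation. Of 82 genes of the cytosolic ribosome, 8 rose (69 adjusted over the list alone), with a median of 0.263 (camera adjusted p = 1.41e-48, adjusted p = 0.188 with an estimated correlation). Lonp1, a protease of the mitochondrial matrix, rose by 0.95 ± 0.13, the single member of 19 mitochondrial chaperones and proteases that passed (camera adjusted p = 0.000335, adjusted p = 0.576 with an estimated correlation). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 1.17 ± 0.19, the single fatty acid oxidation gene of 27 that passed (camera adjusted p = 0.0257, adjusted p = 0.794 with an estimated correlation). Gsta1, a glutathione transferase, rose by 3.59 ± 0.54, the single member that passed among 21 NRF2 and glutathione genes (camera adjusted p = 0.00216, adjusted p = 0.576 with an estimated correlation). The 36 nuclear-encoded subunits of respiratory complex I had 0 called by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Cldn5, a tight junction gene, rose by 1.16 ± 0.24 (adjusted p = 0.0406), the single called member of 15 endothelial markers, whose median was -0.00937 and mean 0.0511, with camera's direction up, so the median differs in sign (camera adjusted p = 0.906, adjusted p = 0.976 with an estimated correlation). The Cldn5 call ended without WT replicate 1, 2 or 3 or Dars2 KO replicate 1, 2 or 3 (adjusted p from 0.0922 to 0.137) and without the low-count filter (adjusted p = 0.0957). Lists with a lower median and no called member that camera called were smooth muscle, fibroblast and sarcomere genes: the medians were -0.194 for 12 smooth muscle and pericyte genes, -0.21 for 18 fibroblast and matrix genes and -0.146 for 24 adult sarcomere genes. Camera gave adjusted p = 0.00137, 0.00594 and 0.000127 for them, and adjusted p = 0.384, 0.752 and 0.395 with an estimated correlation. There were 0 called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) for the smooth muscle genes. The fibroblast genes had 0 called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). The sarcomere genes had 0 called by edgeR (4 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom).

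RNAs of the mitochondrial genome were among the lower genes. Dars2 fell by 2.79 ± 0.34 on the log2 scale (adjusted p = 0.000424). The large mitochondrial ribosomal RNA mt-Rnr2 fell by 1.15 ± 0.19. The mitochondrial tRNA genes mt-Ti, mt-Tq, mt-Tl1, mt-Ta and mt-Ty were lower too (-1.57, -1.34, -1.01, -0.95 and -0.88), with adjusted p between 0.00107 for mt-Ti and 0.0154 for mt-Tq. These tRNA values are uncertain, because mt-Ti and mt-Tq overlap each other on opposite strands, polyA libraries hold few tRNAs, and how the counts treat strand and overlap is not given in the sources used here. Of 13 mitochondrial mRNAs, mt-Nd2 fell by 0.62 ± 0.12 and no other passed over all genes. The transcription factor gene Mycn fell by 0.87 ± 0.20 (adjusted p = 0.0434). Of 15 called genes named without a condition on overlap, 15 showed no overlap between the 4 Dars2 KO and the 4 WT libraries.

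Several of these calls rested on the tool or on single libraries. DESeq2 called 292 genes, and 80 passed without Dars2 KO replicate 1. Limma-voom gave adjusted p = 0.422 for Fgf21 and adjusted p = 0.0773 for Gdf15. Mycn lost its call without any 1 of the 8 libraries (adjusted p from 0.0576 without WT replicate 4 to 0.155 without WT replicate 1). The call of mt-Tq ended without WT replicate 2 or 3 or Dars2 KO replicate 1 or 3 (adjusted p from 0.0556 to 0.074), and that of mt-Ta without Dars2 KO replicate 1 or 3 (adjusted p = 0.0514 and 0.0541). A fit of these groups alone ended the calls of mt-Rnr2 and mt-Tl1 (adjusted p = 0.0652 and 0.0531) and of Ddit3 (adjusted p = 0.0526). Limma-voom gave adjusted p = 0.0512 for Gsta1, and mt-Nd2 lost its call without Dars2 KO replicate 1 or 3 (adjusted p = 0.0521 and 0.0617).

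**Figure D3:**
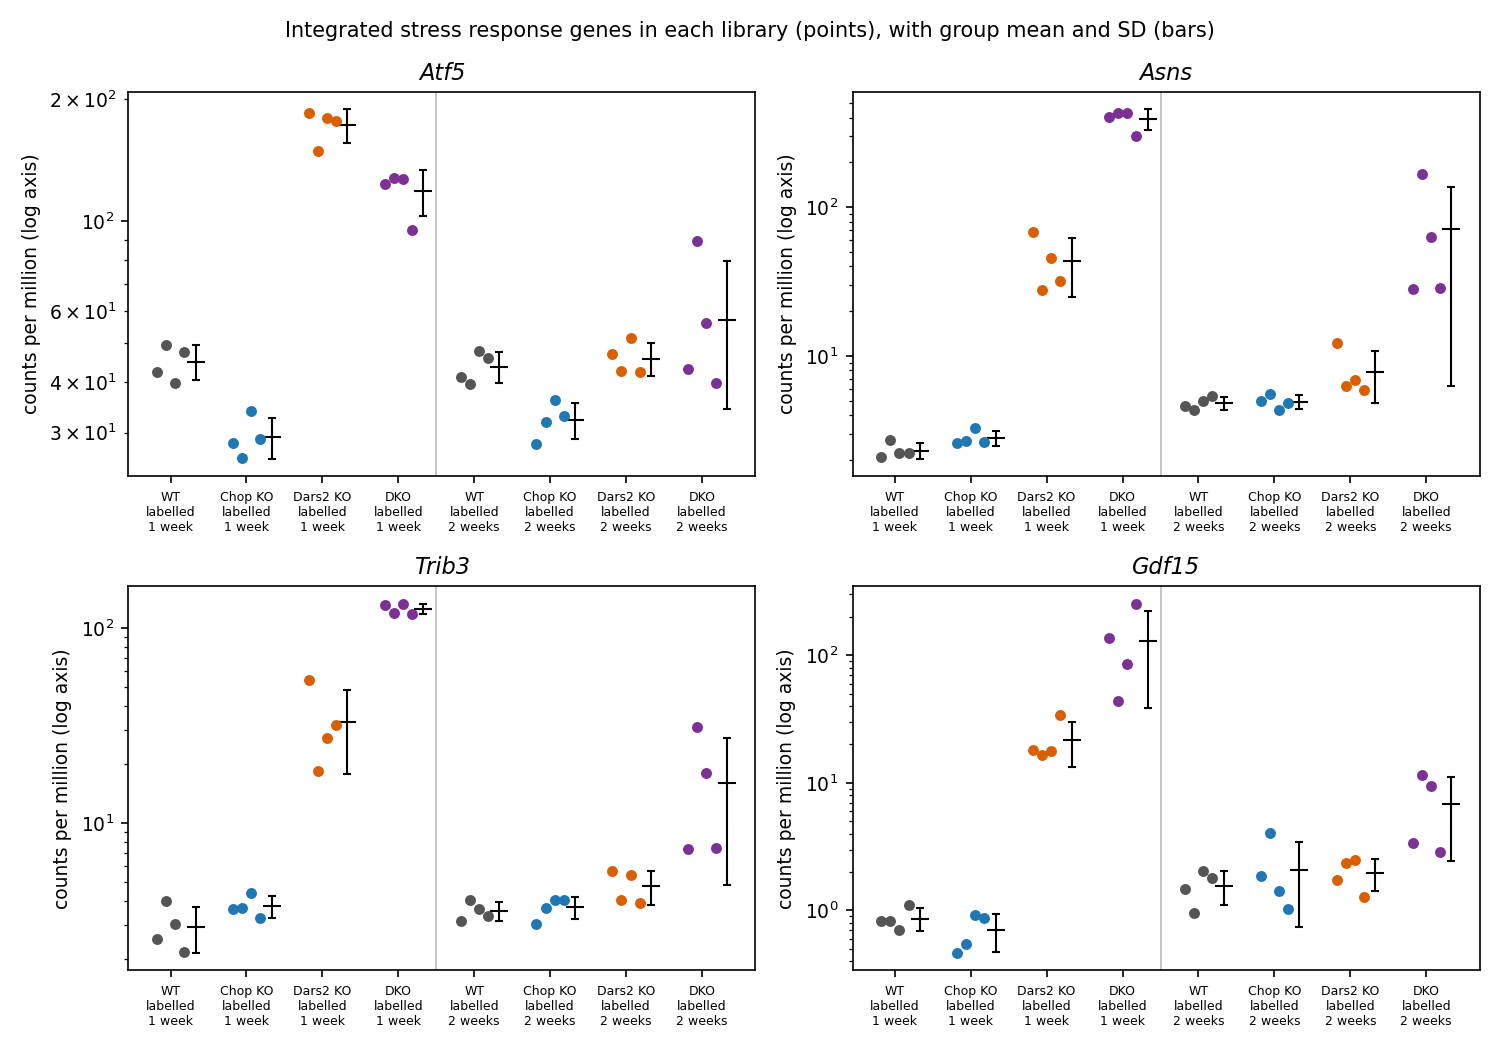
Levels in CPM (log axis) of Atf5, Asns, Trib3 and Gdf15 in each library by labelled age and genotype; points are libraries and bars the mean with SD of 4 libraries. Asns averaged 2.31 CPM in WT, 43.4 CPM in Dars2 KO and 391 CPM in DKO labelled 1 week, against 4.82, 7.84 and 71.6 CPM in the same genotypes labelled 2 weeks.

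In hearts labelled 2 weeks, no gene passed between Dars2 KO and WT. The genes named here first were taken from the comparison labelled 1 week. Gdf15 stood at 1.56 ± 0.464 CPM in WT and 1.97 ± 0.56 CPM in Dars2 KO (log2 change 0.32 ± 0.53, adjusted p = 0.87), and Asns at 4.82 ± 0.465 and 7.84 ± 2.97 CPM (log2 change 0.68 ± 0.54, adjusted p = 0.725). Mthfd2 differed by 0.72 ± 0.48 (adjusted p = 0.68). Dars2 itself differed by -1.26 ± 0.22, with every Dars2 KO library below every WT library, and did not pass either (adjusted p = 0.57), though it did with DESeq2 (adjusted p = 0.000117) and in a fit of these groups alone (adjusted p = 0.00512). By edgeR 0 of 17226 genes passed. At an unadjusted p under 0.05 there were 1290, and DESeq2 called 6 and limma-voom 0. The 34 stress response targets had 0 called by edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). The 24 cell cycle genes had a median of 0.398 higher in Dars2 KO, with 0 called by edgeR (8 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Adjusted over the list alone, 5 rose (camera adjusted p = 8.64e-15, adjusted p = 0.778 with an estimated correlation). The 13 mitochondrial mRNAs had a median of -0.235, with 0 called by edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) (camera adjusted p = 0.000516, adjusted p = 0.778 with an estimated correlation). The 24 genes of cholesterol synthesis had a median of 0.231, with 0 called by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) (camera adjusted p = 2.4e-05, adjusted p = 0.778 with an estimated correlation). Camera called 9 lists, 5 up and 4 down, and 0 with an estimated correlation. Libraries within these groups stood apart: Tnni1, the slow and fetal troponin I, chosen after its values were seen, was at 390 to 618 CPM in WT replicates 1 to 3 and Dars2 KO replicate 3. It was at 676 to 1160 CPM in WT replicate 4 and the other Dars2 KO libraries. Without Dars2 KO replicate 3, 7 genes passed.

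The effect of losing Dars2 was then compared between the labelled ages, with more Dars2 left at the 2 weeks label. The effect on Gdf15 fell by 4.31 ± 0.82, as did those on Mthfd2 (-4.15 ± 0.56), Soat2 (-3.94 ± 0.60) and Asns (-3.52 ± 0.63) on the log2 scale when the effect labelled 1 week was subtracted from that labelled 2 weeks. In edgeR 34 of 17561 genes passed this test, all with the smaller value at the 2 weeks label (adjusted p from 0.000531 for Mthfd2 to 0.0196 for Gdf15 among those named). Of 35 stress response targets, 8 fell (18 adjusted over the list alone); camera adjusted p = 1.45e-24, adjusted p = 0.0499 with an estimated correlation. Of 20 cytosolic aminoacyl-tRNA synthetases, 3 fell (11 adjusted over the list alone); camera adjusted p = 1.44e-11, adjusted p = 0.58 with an estimated correlation. Limma-voom called 13 genes, 3 stress response targets and 1 cytosolic synthetase among them, with adjusted p = 0.457 for Gdf15 and adjusted p = 0.264 for Asns. Between 14 and 22 genes passed without WT labelled 1 week replicate 1, 2, 3 or 4, Dars2 KO labelled 1 week replicate 1, WT labelled 2 weeks replicate 1, 3 or 4, or Dars2 KO labelled 2 weeks replicate 2 or 4. The call of Gdf15 ended without WT labelled 1 week replicate 1, 2 or 3, WT labelled 2 weeks replicate 3 or 4, or Dars2 KO labelled 2 weeks replicate 4 (adjusted p from 0.0514 to 0.0566).

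In hearts labelled 1 week, DKO and Dars2 KO differed in 50.1% of the genes measured, in both directions. Crlf1, a secreted cytokine partner, rose by 5.53 ± 0.42 in DKO against Dars2 KO. Dhrs9, of the retinol dehydrogenase family, rose by 5.45 ± 0.58, and the ketone body enzyme Bdh1 by 5.34 ± 0.42. The vasoactive peptide gene Edn3 rose by 5.17 ± 0.51, the metalloprotease gene Adamts16 by 5.09 ± 0.56 and the bicarbonate transporter gene Slc4a10 by 6.50 ± 0.59. Slc7a11, which exchanges cystine for glutamate (GRCm38 chromosome 3, 49892526 to 50443614), rose by 4.98 ± 0.46. Cntnap3, an adhesion protein of the neurexin family, went from 1 to 530 counts over the group, a ratio of 528 with a 95% counting interval of 94.3 to 20900. In the other direction, Lrat, which esterifies retinol, fell by 5.65 ± 0.61, as did the carboxylesterase gene Ces1d (-5.37 ± 0.54). The kinase gene Sbk3 fell by 5.83 ± 1.18, as did its neighbour Sbk2 (-4.93 ± 0.97), the protease gene Prss55 (-5.19 ± 0.54) and the lectin gene Clec18a (-4.84 ± 0.40). Vmn2r3 went from 952 counts in Dars2 KO to 2 in DKO, a ratio of 478 (132 to 3950), and the aldehyde dehydrogenase gene Aldh3b3 from 226 to 2, a ratio of 113 (31.1 to 943). Sbk2 overlaps Ssc5d on the other strand, and Prss55 and Vmn2r3 belong to gene families, so their counts are uncertain. In edgeR 8173 of 16324 genes passed, 4182 higher and 3991 lower in DKO (adjusted p among those named from 3.36e-08 for Crlf1 to 0.00134 for Aldh3b3).

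Most targets of the stress response were higher in DKO than in Dars2 KO labelled 1 week. Of 35 stress response targets, 29 rose and 2 fell (29 and 2 adjusted over the list alone), with a median of 1.92 (camera adjusted p = 3.4e-14, adjusted p = 0.0608 with an estimated correlation). Among them, Cars, the cytosolic cysteinyl-tRNA synthetase, rose by 2.08 ± 0.10, Eif4ebp1, a brake on translation, by 2.01 ± 0.12 and Slc7a5 by 2.87 ± 0.17. Gdf15 rose by 2.54 ± 0.43 to 129 ± 90.9 CPM, Fgf21 by 3.01 ± 0.50 and Asns by 3.16 ± 0.23 to 391 ± 62.5 CPM. The targets that fell were Atf5, named here after its values were seen, from 172 ± 16.3 to 118 ± 15.6 CPM (-0.56 ± 0.10, adjusted p = 0.000275), and Ddit3, the gene targeted in DKO (-0.59 ± 0.15, adjusted p = 0.00323). Dars2 differed by -0.13 ± 0.36 (adjusted p = 0.779). Of 18 genes of serine, glycine and folate metabolism, 12 rose and 3 fell (12 and 3 adjusted over the list alone), including Shmt2 (2.43 ± 0.14), Phgdh (3.64 ± 0.22) and Psph (2.94 ± 0.20), enzymes of serine synthesis and use (camera adjusted p = 0.00131, adjusted p = 0.243 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 18 rose and 1 fell (18 and 1 adjusted over the list alone), among them Tars (1.58 ± 0.08) and Nars (1.92 ± 0.11; camera adjusted p = 4.05e-13, adjusted p = 0.302 with an estimated correlation). Of 82 genes of the cytosolic ribosome, 77 rose and 1 fell (78 and 1 adjusted over the list alone), with a median of 0.511 (camera adjusted p = 7.09e-21, adjusted p = 0.503 with an estimated correlation). Of 21 NRF2 and glutathione genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone), including the heme-degrading Hmox1 (2.95 ± 0.20) and the thioredoxin reductase Txnrd1 (1.44 ± 0.15; camera adjusted p = 9.14e-05, adjusted p = 0.503 with an estimated correlation). Of 20 genes of p53 signalling and apoptosis, 12 rose and 1 fell (12 and 1 adjusted over the list alone), including the survival gene Bcl2 (1.79 ± 0.14; camera adjusted p = 0.000228, adjusted p = 0.25 with an estimated correlation).

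Most called genes of the respiratory chain, of fatty acid oxidation and of the sarcomere were lower in DKO in the same comparison, and no list of this paragraph kept a camera call with an estimated correlation. Of 36 nuclear-encoded subunits of respiratory complex I, 1 rose and 18 fell (1 and 18 adjusted over the list alone), for example Ndufv3 (-0.66 ± 0.06) and Ndufs1 (-0.65 ± 0.07). Of 15 subunits of the ATP synthase, 8 fell (8 adjusted over the list alone). Of 16 subunits of complex IV, 2 rose and 8 fell (3 and 10 adjusted over the list alone), with Cox7a1, a muscle isoform, falling (-1.32 ± 0.12) and Cox6a1, the isoform of other tissues, rising by 1.22 ± 0.12. Of 27 fatty acid oxidation genes, 16 fell (18 adjusted over the list alone), for example Acads (-0.78 ± 0.08) and Hadh (-0.80 ± 0.08). Of 20 genes of the tricarboxylic acid cycle, 2 rose and 9 fell (2 and 9 adjusted over the list alone). Of 24 adult sarcomere and calcium handling genes, 4 rose and 17 fell (4 and 17 adjusted over the list alone), with lower myoglobin (Mb, -1.05 ± 0.10), calcium pump (Atp2a2, -0.96 ± 0.10) and adult troponin I (Tnni3, -0.71 ± 0.08). Camera gave adjusted p from 0.00029 for the sarcomere genes to 0.0249 for complex IV among these lists, and adjusted p from 0.503 to 0.714 with an estimated correlation. Of 20 glycolysis genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone). They included the glucose transporter gene Slc2a1, rising by 2.26 ± 0.19, and the muscle phosphofructokinase gene Pfkm, falling (-0.90 ± 0.09) (camera adjusted p = 0.00191, adjusted p = 0.596 with an estimated correlation). Of 19 cardiac stress and fetal genes, 10 rose (10 adjusted over the list alone), including Fhl1 (2.55 ± 0.22) and Uck2 (2.55 ± 0.19; camera adjusted p = 0.00131, adjusted p = 0.503 with an estimated correlation). The 13 mitochondrial mRNAs had a median of -0.236, of which 1 rose and 4 fell (0 and 4 adjusted over the list alone) (camera adjusted p = 0.326, adjusted p = 0.873 with an estimated correlation).

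Cell type and cell cycle lists held called members too, where 50.1% of all genes were called, and none of those given kept a camera call with an estimated correlation. Of 16 macrophage and myeloid markers, 8 rose (8 adjusted over the list alone), such as the neutrophil calcium-binding protein gene S100a8 (2.48 ± 0.60; camera adjusted p = 0.0193, adjusted p = 0.714 with an estimated correlation). Of 24 cell cycle genes, 18 rose (18 adjusted over the list alone) (camera adjusted p = 0.0193, adjusted p = 0.845 with an estimated correlation). Limma-voom called 8 of them higher and 1 lower, and in edgeR 13 to 19 rose with each library left out in turn, with 1 lower without DKO replicate 4. The DKO libraries differed in these genes: Hmmr, chosen after its values were seen, ranged from 0.384 to 4.43 CPM around a mean of 2.94. Of 18 fibroblast and matrix markers, 9 rose and 4 fell (9 and 4 adjusted over the list alone), with the matrix gene Postn at 2.48 ± 0.25 and the protease inhibitor gene Timp1 at 3.03 ± 0.40 (camera adjusted p = 0.282, adjusted p = 0.883 with an estimated correlation). Of 10 atrial markers, 3 fell (3 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 0.0791, adjusted p = 0.774 with an estimated correlation). Of 33 called genes named without a condition on overlap, 32 showed no overlap between the 4 DKO and the 4 Dars2 KO libraries, and for S100a8 3 of 4 libraries of each group lay outside the range of the other. Limma-voom gave adjusted p = 0.0507 for Sbk3.

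At the 2 weeks label few genes differed between DKO and Dars2 KO, and whether stress genes were among them depended on the tool and the fit. Dars2 itself stood lower in DKO, at 2.592 to 4.215 CPM against 5.298 to 6.606 CPM in Dars2 KO. Loss of Chop and the lower Dars2 level therefore cannot be told apart in this comparison. Fgf21 rose by 4.10 ± 0.69, Chac1, which degrades glutathione, by 3.55 ± 0.58, Asns by 3.23 ± 0.53 and Phgdh by 3.00 ± 0.47, with Gpt2, a mitochondrial alanine transaminase, at 0.79 ± 0.15. The water channel gene Aqp8 rose by 1.94 ± 0.32, Pcdhga8 by 1.45 ± 0.29 and mt-Co3 by 1.22 ± 0.19. Lower in DKO were the blood group genes Rhd (-1.73 ± 0.32) and Art4 (-0.50 ± 0.09). So were Nlrp10 (-1.32 ± 0.20), Aldh16a1 (-0.93 ± 0.16), Gsg1l (-0.91 ± 0.13), Hspa12a (-0.66 ± 0.10), the slow skeletal troponin T gene Tnnt1 (-0.60 ± 0.11) and the ubiquitin ligase gene Rnf41 (-0.49 ± 0.07). Means in Chop KO labelled 2 weeks also lay below WT for Rhd (2.28 against 4.63 CPM), Aldh16a1 (20.8 against 27.1), Nlrp10 (17.5 against 23) and Hspa12a (39.5 against 50.7). These 4 genes overlapped in range there and did not pass. Gsg1l (24.6 against 28.2) and Art4 (14.4 against 15) differed less. Pcdhga8 (ENSMUSG00000103897, a symbol that another gene identifier shares), mt-Co3, Aldh16a1 and Hspa12a overlap other genes, so their counts are uncertain. In edgeR 34 of 17226 genes passed, 18 higher and 16 lower, with adjusted p from 0.0238 for Rnf41 to 0.0496 for Pcdhga8 among those named, and 2274 were at an unadjusted p under 0.05. Of 34 stress response targets, 5 rose (21 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 2.89e-19, adjusted p = 0.655 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 0 were called by edgeR (10 at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma-voom). Of them, adjusted over the list alone, 10 rose (camera adjusted p = 5.43e-08, adjusted p = 0.655 with an estimated correlation). The 24 cell cycle genes had a median of -0.424, with 0 called by edgeR (11 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom). With p adjusted over the list alone, 4 fell (camera adjusted p = 2.36e-11, adjusted p = 0.655 with an estimated correlation). Camera called 16 lists here, 11 up and 5 down, and 0 with an estimated correlation. In these groups Tnni1 stood at 322 CPM in DKO replicate 2 against 856 to 1140 CPM in the other DKO and the Chop KO libraries, and at 390 to 618 CPM in Dars2 KO replicate 3 with WT replicates 1 to 3.

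Nearly all of this comparison hung on single libraries, and every named gene lost its call under at least 1 of them. No gene passed without Dars2 KO replicate 2 or 4, 7 passed without Dars2 KO replicate 1, 5 without DKO replicate 3 and 20 without DKO replicate 2, while 86 passed without Dars2 KO replicate 3 and 68 without DKO replicate 4. DESeq2 called 349 genes, edgeR without the low-count filter 54 and a fit of these groups alone 14, of which 1 was higher and 13 lower. In that fit Fgf21, Phgdh, Chac1, Gpt2 and Asns did not pass (adjusted p from 0.185 for Fgf21 to 0.242 for Asns). Limma-voom called 26 genes, 9 higher and 17 lower, with 0 stress response targets and adjusted p from 0.059 for Gpt2 to 0.141 for Chac1 among these. Of the genes higher in DKO, 12 of 18 were also higher in the same comparison labelled 1 week, where 4.63 would fall by chance (exact hypergeometric test, p = 0.000306). Of the lower genes, 14 of 16 were also lower there, where 3.92 would fall by chance (exact p = 1.97e-07). The test of the difference between the ages called 6377 of 17561 genes in edgeR, 3192 higher and 3185 lower at the 2 weeks label. There, Dhrs9 fell by 6.14 ± 0.96, as did the keratinocyte protein gene Sprr1a (-6.09 ± 1.35), Crlf1 (-5.95 ± 0.72) and the stretch-responsive muscle gene Ankrd2 (-5.91 ± 1.10). Lrat rose by 7.05 ± 0.88, Clec18a by 5.50 ± 0.79 and Aldh3b3 by 5.36 ± 1.70, a fitted value that rests on 2 counts over the DKO group labelled 1 week. Htr3a, a serotonin receptor gene, also passed (adjusted p = 0.0393), but its DKO group labelled 1 week held 0 counts. It lost its call without any 1 of 10 libraries: Dars2 KO labelled 1 week replicate 2, each DKO labelled 1 week, Dars2 KO labelled 2 weeks replicate 2, 3 or 4 and DKO labelled 2 weeks replicate 1 or 4 (adjusted p from 0.0528 to 0.146). Limma-voom gave adjusted p = 0.345 for Htr3a, 0.106 for Aldh3b3 and 0.0503 for Ankrd2.

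Few genes differed between Chop KO and WT. At the 1 week label, Pcp4, a calmodulin-binding protein gene, rose by 2.20 ± 0.36 in Chop KO, the metal-binding metallothionein genes Mt2 and Mt1 by 1.54 ± 0.27 and 1.01 ± 0.19, and the cation channel gene Trpv4 by 0.93 ± 0.17. Lrat fell by 1.91 ± 0.37, as did the actin-severing gene Scin (-1.35 ± 0.22), the phagocyte oxidase gene Cybb (-1.02 ± 0.16) and the myelin and lymphocyte protein gene Mal (-0.80 ± 0.15). In edgeR 26 of 16324 genes passed, 16 higher and 10 lower, with adjusted p from 0.0222 for Cybb to 0.0487 for Lrat among those named. Of 35 stress response targets, 0 rose and 1 fell (2 and 2 adjusted over the list alone): Atf5 fell by 0.58 ± 0.11 (camera adjusted p = 0.249, adjusted p = 0.854 with an estimated correlation). The 16 macrophage and myeloid markers had a median of -0.437, with 0 called by edgeR (10 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom). Adjusted over the list alone, 8 fell (camera adjusted p = 1.16e-07, adjusted p = 0.854 with an estimated correlation). The 8 erythroid markers had a median of -0.707, with 0 called by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) (camera adjusted p = 0.0307, adjusted p = 0.854 with an estimated correlation). The 10 atrial markers had a median of -0.871, with 0 called by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) (camera adjusted p = 0.0464, adjusted p = 0.854 with an estimated correlation). The 23 interferon-stimulated genes had a median of -0.29, with 0 called by edgeR (6 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) (camera adjusted p = 0.000126, adjusted p = 0.854 with an estimated correlation). Camera called 13 lists in this comparison, 8 up and 5 down, and 0 with an estimated correlation. Those up were 4 lists of respiratory chain and ATP synthase subunits, the mitochondrial ribosome, fatty acid oxidation, glycolysis and adult sarcomere genes, with medians from 0.0599 for the mitochondrial ribosome to 0.122 for complex III (camera adjusted p from 3.42e-05 for complex I to 0.0455 for complex IV, and adjusted p = 0.854 with an estimated correlation). The 36 complex I subunits had a median of 0.0997, with 0 called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Leaving out WT replicate 1, 3 or 4 or Chop KO replicate 4 left 1 gene, leaving out Chop KO replicate 3 left 3, and 54 and 63 passed without WT replicate 2 and without Chop KO replicate 2. DESeq2 called 290 genes and limma-voom 42, and each named gene lost its call under at least 1 left-out library.

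At the 2 weeks label, Rnf41 was the single gene of 17226 that passed edgeR's test between Chop KO and WT, lower by -0.61 ± 0.07 in Chop KO (adjusted p = 0.00168; GRCm38 chromosome 10, 128411657 to 128441441), with 2166 genes at an unadjusted p under 0.05. Rnf41 lies near Ddit3 and, in values looked up after this one was seen, stood at -0.64 ± 0.10 in DKO against Dars2 KO labelled 1 week (adjusted p = 7.21e-05) and at -0.49 ± 0.07 labelled 2 weeks (adjusted p = 0.0238). In Chop KO against WT labelled 1 week it stood at -0.47 ± 0.10 (adjusted p = 0.0675; adjusted p = 0.00697 with DESeq2 and adjusted p = 0.0205 in a fit of these groups alone). The 83 cytosolic ribosome genes had a median of 0.114, with 0 called by edgeR (17 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom) (camera adjusted p = 1.97e-14, adjusted p = 0.921 with an estimated correlation). The 13 mitochondrial mRNAs had a median of -0.288, with 0 called by edgeR (7 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom) (camera adjusted p = 0.0187, adjusted p = 0.921 with an estimated correlation). Adjusted over the list alone, 1 rose and 5 fell. Tnni1 stood at 390 to 618 CPM in WT replicates 1 to 3 and at 856 to 1140 CPM in Chop KO. Loss of Chop was not told apart from this difference. Camera called 6 lists, 1 up and 5 down, and 0 with an estimated correlation. DESeq2 called 297 genes, and 2, 5 and 15 passed without WT replicate 3, WT replicate 4 or Chop KO replicate 1. By edgeR 0 genes were called in Chop KO against WT at both ages.

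**Figure D4:**
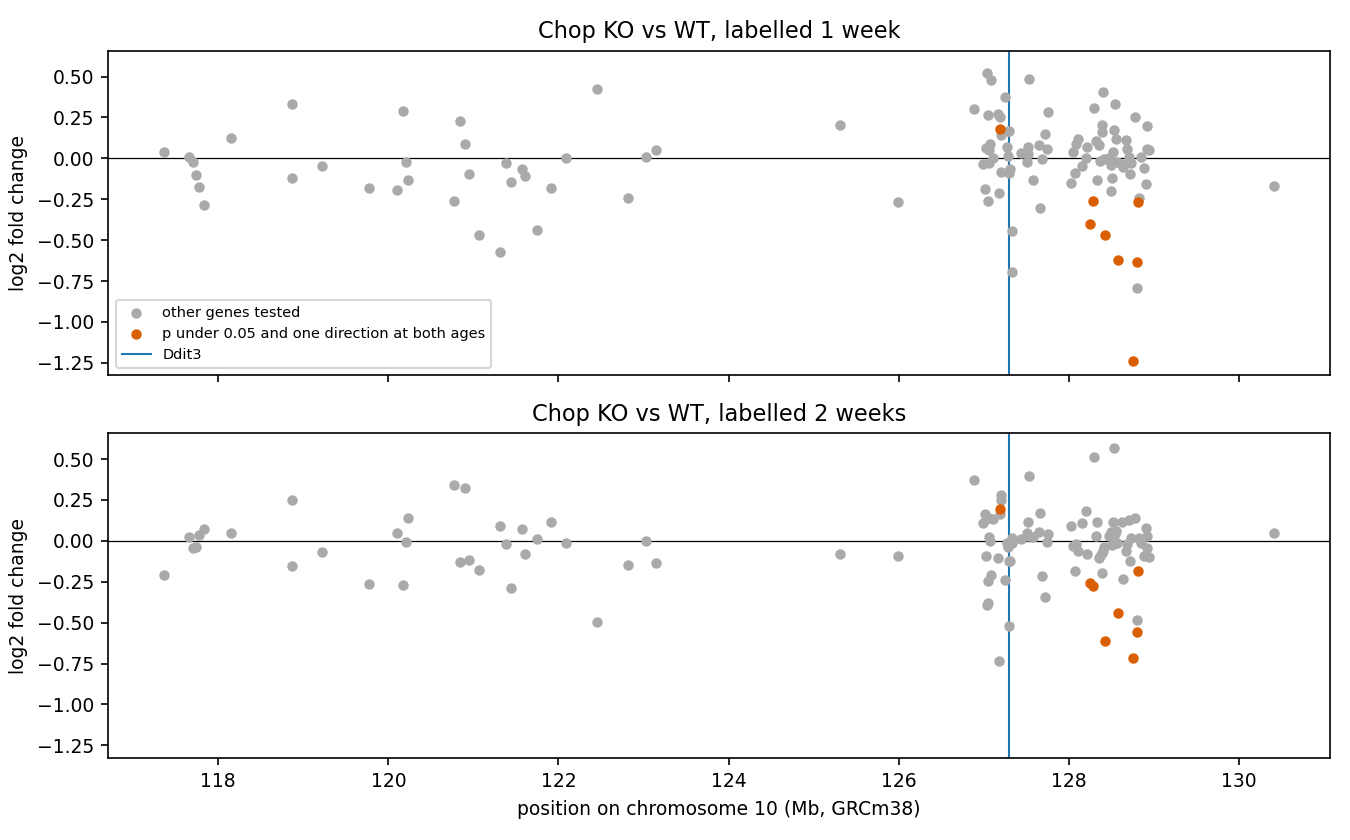
Map of GRCm38 chromosome 10 around Ddit3 (vertical line), with position in megabases on the x axis and log2 change of Chop KO against WT on the y axis for the tested genes, labelled 1 week in 1 panel and 2 weeks in the next. Orange points are the genes at an unadjusted p under 0.05 with the same sign at both ages. Rnf41 sits at -0.47 and -0.61.

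In mice without Chop, loss of Dars2 gave the highest number of called genes of the comparisons between genotypes, 8815 at the 1 week label. Fgf21 went from 1 count over the Chop KO group to 2681 in DKO, a ratio of 2640 with a 95% counting interval of 473 to 104000. Cntnap3 went from 0 to 530 counts, at least 174-fold against the floor of 3 counts over the group, and Slc4a10 from 1 to 861, a ratio of 848 (152 to 33500). Adm2 rose by 9.19 ± 0.39, Slc7a11 by 7.60 ± 0.58, Gdf15 by 7.45 ± 0.59, Asns by 7.06 ± 0.28, Phgdh by 6.81 ± 0.26 and Mthfd2 by 6.73 ± 0.25. Lower were Prss55 (-5.77 ± 0.53), Ces1d (-5.60 ± 0.54), mt-Ti (-5.83 ± 0.29) and Fam188b2, from 217 to 2 counts, a ratio of 110 (30.1 to 916). Dars2 fell by 2.08 ± 0.34 (adjusted p = 0.000106). In edgeR 8815 of 16324 genes passed, 4593 higher and 4222 lower, with adjusted p from 2.56e-11 for Adm2 to 1.57e-06 for Ces1d among those of this paragraph other than Dars2. Of 11 called genes named for this comparison without a condition on overlap, 11 showed no overlap between the 4 DKO and 4 Chop KO libraries.

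Between Chop KO and DKO labelled 1 week, most stress response targets were higher and most complex I, ATP synthase and sarcomere genes lower. Of 35 stress response targets, 30 rose and 0 fell (30 and 1 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 2.24e-16, adjusted p = 0.0377 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 18 rose and 1 fell (18 and 1 adjusted over the list alone) (camera adjusted p = 8.05e-14, adjusted p = 0.304 with an estimated correlation). Of 21 NRF2 and glutathione genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone) (camera adjusted p = 1.76e-05, adjusted p = 0.321 with an estimated correlation). Of 36 complex I subunits, 28 fell (29 adjusted over the list alone) (camera adjusted p = 2.64e-07, adjusted p = 0.615 with an estimated correlation). Of 15 ATP synthase subunits, 11 fell (11 adjusted over the list alone) (camera adjusted p = 0.000205, adjusted p = 0.615 with an estimated correlation). Of 19 cardiac stress and fetal genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone). Among them were the natriuretic peptide gene Nppa at 3.54 ± 1.02, the stretch-responsive Ankrd1 at 3.76 ± 0.30 and Xirp2 at 3.27 ± 0.26 (camera adjusted p = 8.43e-05, adjusted p = 0.321 with an estimated correlation). Of 24 adult sarcomere genes, 4 rose and 20 fell (4 and 20 adjusted over the list alone) (camera adjusted p = 1.53e-06, adjusted p = 0.304 with an estimated correlation). Of 16 macrophage and myeloid markers, 16 rose (16 adjusted over the list alone), among them Fcgr1 (1.39 ± 0.21) and Cd68 (1.01 ± 0.17; camera adjusted p = 0.000533, adjusted p = 0.596 with an estimated correlation). The 13 mitochondrial mRNAs had a median of 0.141 and a mean of 0.0984 while camera's direction was down, so these differ in sign (camera adjusted p = 0.776, adjusted p = 0.951 with an estimated correlation).

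Genes changed by loss of Dars2 with Chop present were shared with those changed by loss of Dars2 without it, in comparisons that have no library in common. Of 106 genes higher in Dars2 KO than in WT labelled 1 week, 96 were also higher in DKO than in Chop KO, where 29.8 would fall by chance (exact hypergeometric test, p = 8.47e-42). Of 19 lower genes, 18 were also lower, where 4.91 would fall by chance (exact p = 3.75e-10). Loss of Chop was compared in the same way with and without Dars2: 7 of 16 genes higher in Chop KO than in WT labelled 1 week were also higher in DKO than in Dars2 KO, where 4.1 would fall by chance (exact p = 0.0889). Of 10 lower genes 7 were also lower, where 2.44 would fall by chance (exact p = 0.00305), and 6 genes were higher in Chop KO than in WT and lower in DKO than in Dars2 KO.

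At the 2 weeks label, 5 of the 8 genes higher in DKO than in Chop KO were targets of the stress response. Fgf21 rose by 5.98 ± 0.84, Adm2 by 4.85 ± 0.82, Chac1 by 4.67 ± 0.63, Asns by 3.91 ± 0.56, Phgdh by 3.43 ± 0.48 and Mthfd2 by 3.43 ± 0.50. In edgeR 8 of 17226 genes passed, all higher in DKO, with adjusted p from 0.0354 for Fgf21 to 0.0427 for Adm2 among the named ones, and 1783 were at an unadjusted p under 0.05. All 8 were also higher in the same comparison labelled 1 week, where 2.26 would fall by chance (exact hypergeometric test, p = 4.04e-05). Of 34 stress response targets, 5 rose (22 adjusted over the list alone), with a median of 0.503 (camera adjusted p = 5.93e-22, adjusted p = 0.153 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, 0 were called by edgeR (15 at an unadjusted p under 0.05, 9 by DESeq2 and 0 by limma-voom). With p adjusted over the list alone, 13 rose (camera adjusted p = 2.52e-16, adjusted p = 0.153 with an estimated correlation). The 10 atrial markers had a median of -0.761, with 0 called by edgeR (7 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). Adjusted over the list alone, 5 fell (camera adjusted p = 6.6e-08, adjusted p = 0.184 with an estimated correlation). The 18 fibroblast and matrix markers had a median of -0.227, with 0 called by edgeR (11 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom). For these 10 fell when adjusted over the list alone (camera adjusted p = 2.15e-10, adjusted p = 0.153 with an estimated correlation). Camera called 23 lists in this comparison, 18 up and 5 down, and 0 with an estimated correlation. A fit of these groups alone called 2 genes, 0 higher and 2 lower, with none of the 8 among them (adjusted p from 0.0547 for Fgf21 to 0.204 for Asns among the named ones). The 8 calls rested on most of the libraries: 0 genes passed without Chop KO replicate 1, 2 or 4 or DKO replicate 3, and 1 without Chop KO replicate 3, while 16, 13 and 27 passed without DKO replicate 1, 2 and 4. DESeq2 called 187 genes and limma-voom 0, and 0 genes passed with sex as a covariate, labelled or read from the transcripts.

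Whether the effect of losing Dars2 differed with and without Chop was tested as an interaction. At the 1 week label, Slc4a10 was 7.99 ± 2.05, Dhrs9 6.54 ± 0.96, Crlf1 6.31 ± 0.67 and Sprr1a 6.10 ± 1.85 higher in DKO on the log2 scale than the sum of the separate losses. Pcp4 (-6.49 ± 0.62), Ces1d (-5.48 ± 0.67), Clec18a (-5.43 ± 0.48) and Fam188b2 (-5.42 ± 0.89) were lower than that sum. The fitted values of Slc4a10 and Sprr1a rest on 1 count over the Chop KO group (and for Sprr1a 3 over WT) and that of Fam188b2 on 2 over the DKO group, and Slc4a10 lost its call without WT replicate 1 (adjusted p = 0.146). In edgeR 5735 of 16324 genes passed, 2965 positive and 2770 negative, with adjusted p from 8.74e-07 for Clec18a to 0.0162 for Sprr1a among those named so far. Of 35 stress response targets, 25 were positive and 1 were negative (26 and 1 adjusted over the list alone), for example Cars (1.90 ± 0.14), Eif4ebp1 (1.94 ± 0.16) and Slc7a5 (2.68 ± 0.24; camera adjusted p = 3.12e-11, adjusted p = 0.156 with an estimated correlation). Ddit3 itself was at -0.76 ± 0.21 (adjusted p = 0.0101). Of 36 complex I subunits, 17 were negative (20 adjusted over the list alone), such as Ndufv3 (-0.72 ± 0.08; camera adjusted p = 2.07e-06, adjusted p = 0.637 with an estimated correlation). Of 24 adult sarcomere genes, 4 were positive and 17 were negative (4 and 17 adjusted over the list alone), such as the potassium channel gene Kcnj2 (-1.98 ± 0.22; camera adjusted p = 1.46e-05, adjusted p = 0.347 with an estimated correlation). Of 27 fatty acid oxidation genes, 14 were negative (16 adjusted over the list alone) (camera adjusted p = 1.5e-05, adjusted p = 0.621 with an estimated correlation). Of 19 cardiac stress and fetal genes, 10 were positive (11 adjusted over the list alone) (camera adjusted p = 7.5e-05, adjusted p = 0.347 with an estimated correlation). Of 16 macrophage and myeloid markers, 14 were positive (16 adjusted over the list alone) (camera adjusted p = 7.18e-05, adjusted p = 0.466 with an estimated correlation).

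At the 2 weeks label 0 of 17226 genes passed the interaction test in edgeR. At an unadjusted p under 0.05 there were 1443, and DESeq2 called 2 and limma-voom 0. The 34 stress response targets had a median of 0.599, with 0 called by edgeR (16 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom). Of them, adjusted over the list alone, 10 were positive (camera adjusted p = 1.02e-13, adjusted p = 0.672 with an estimated correlation). The 20 cytosolic aminoacyl-tRNA synthetases had a median of 0.297, with 0 called by edgeR (9 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). With p adjusted over the list alone, 6 were positive (camera adjusted p = 3.82e-06, adjusted p = 0.672 with an estimated correlation). The 24 cell cycle genes had a median of -0.459, with 0 called by edgeR (4 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom) (camera adjusted p = 4.51e-10, adjusted p = 0.672 with an estimated correlation). The 39 lists differed in how far camera's calls held: with an estimated correlation, 2 lists kept a call in Dars2 KO against WT, 1 in DKO against Chop KO and 0 in the other comparisons of genotypes labelled 1 week, and 0 in any labelled 2 weeks.

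**Figure D5:**
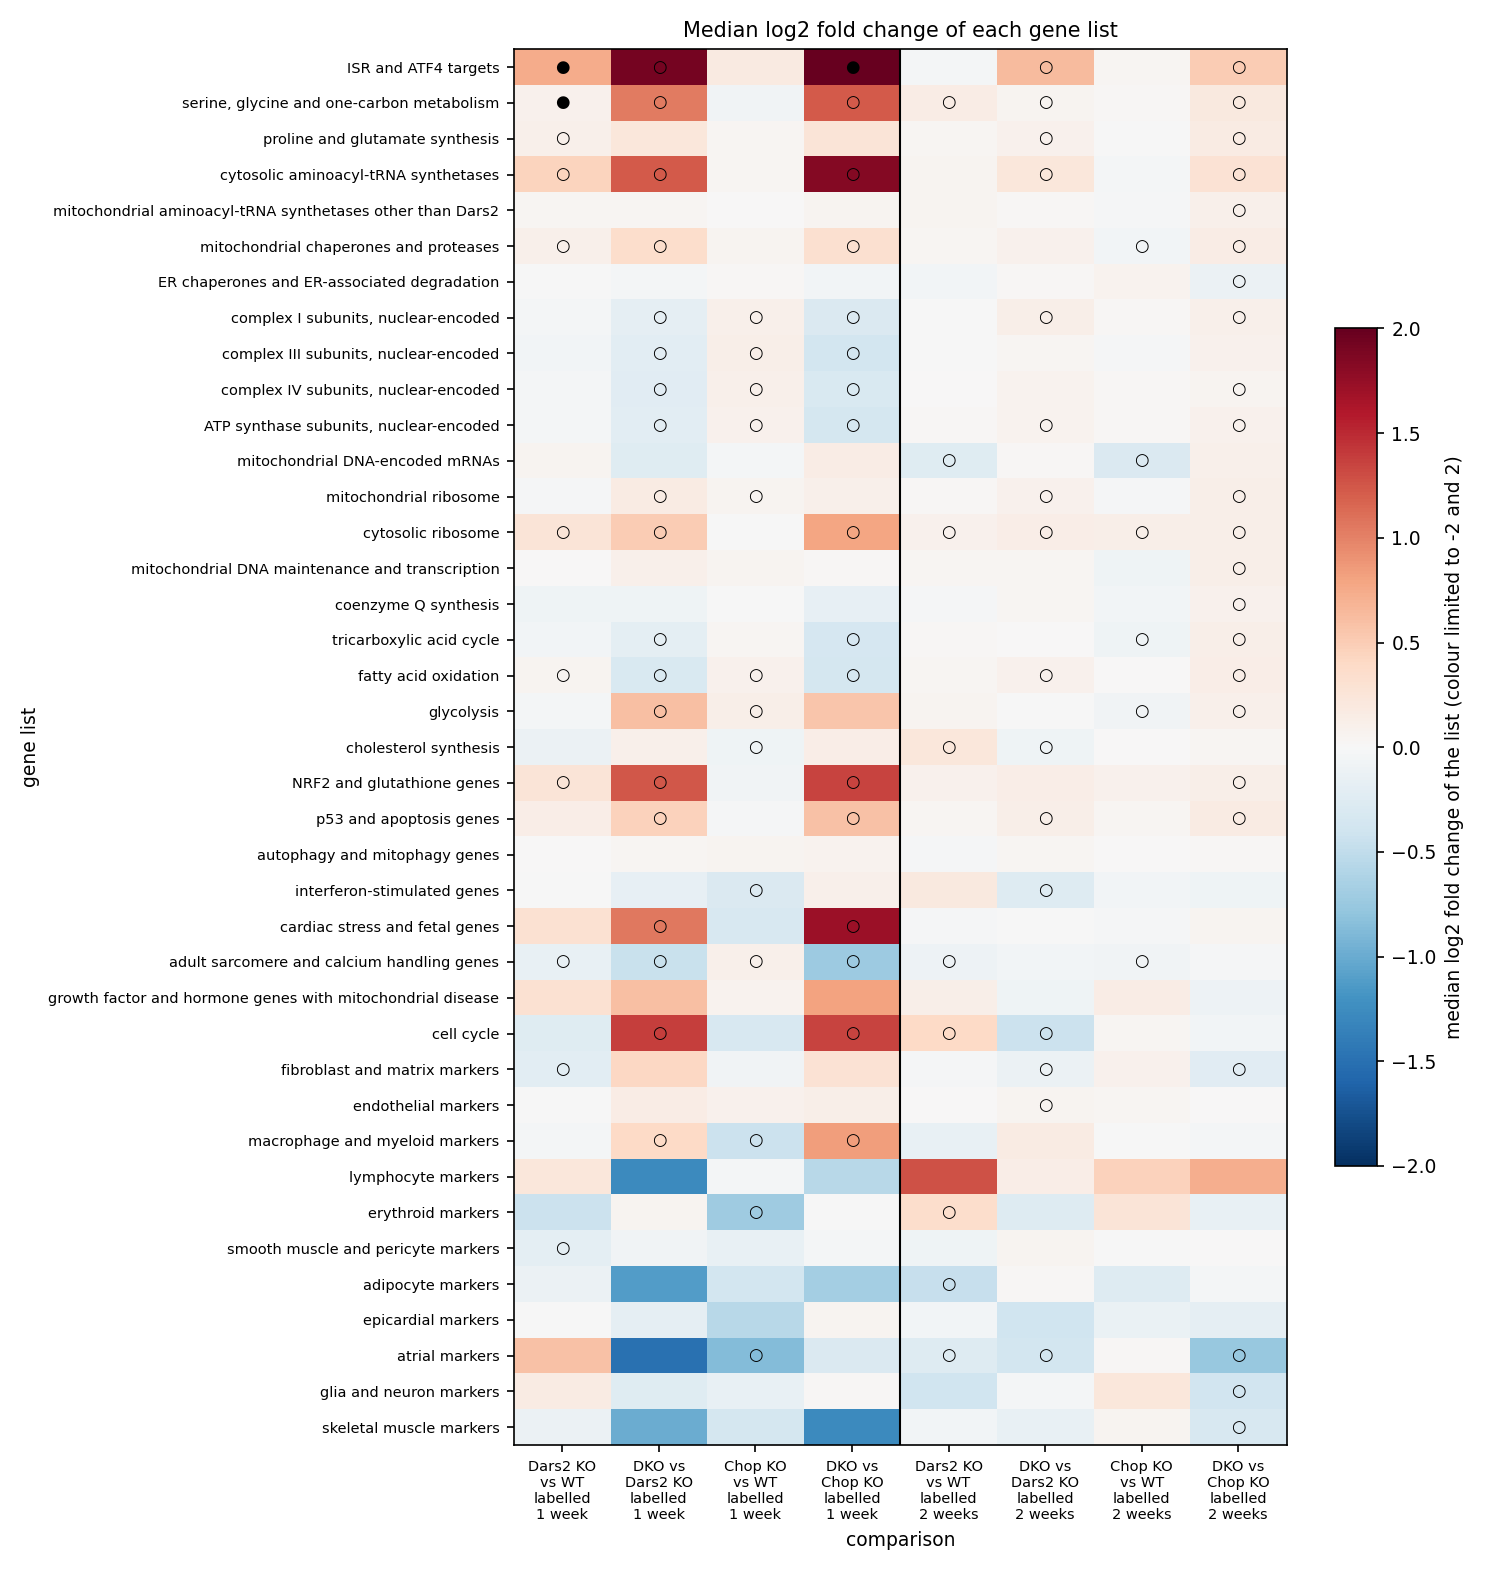
Median log2 change of each of the 39 gene lists (y axis) in the 8 comparisons of genotypes (x axis), colour limited to -2 and 2. Filled circles mark camera adjusted p under 0.05 with the preset and the estimated correlation, open circles with the preset only. The stress response list had medians of 0.748, 1.92 and 2.64 in Dars2 KO against WT, DKO against Dars2 KO and DKO against Chop KO labelled 1 week, and of 0.63 and 0.503 in DKO against Dars2 KO and against Chop KO labelled 2 weeks.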

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

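Chosen only after the result was seen were the tests of the sex transcripts, of sequencing depth, of DKO tissue in place of Chop KO tissue and of the genes near Ddit3. The splits of the libraries, the cell cycle list, the genes near Dars2 and the floxed allele were set before their results were seen.

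The response to loss of Dars2 was larger in libraries labelled 1 week than in those labelled 2 weeks, the reverse of a condition that advances from an early to a late stage. Read as labelled, a receding response needs a postnatal fall of the cell cycle genes from 1 to 2 weeks, but their median was 3.38 higher on the log2 scale in WT labelled 2 weeks than in WT labelled 1 week. Lower depth is argued against by a ratio of median totals, 2 weeks over 1 week, of 1.13. Xist and Y-linked transcripts matched the sex label of the same genotype and replicate number at the other age in 32 of 32 libraries and their own in 10. This is consistent with the hypothesis that age, sex and animal labels were exchanged between the projects, in which case the libraries labelled 1 week would be the older hearts. Tnni1, the fetal and slow troponin I, chosen after its values were seen, stood at 322 to 1160 CPM labelled 2 weeks and at 0.498 to 7.44 CPM labelled 1 week. With the cell cycle genes this argues against the order of ages as labelled. The project code coincides with the labelled age, so a difference in how the libraries were made stays open for the size of the response. Such a difference could not give the match of sex to the other labels in 32 of 32 libraries. A biological change with age also stays open and was not tested apart from the project.

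Dars2 was lower in Chop KO libraries, which carry no Cre by the labels, than in WT, a difference that did not pass edgeR's test at either age. DKO tissue in their place is argued against by the stress response list, whose median in Chop KO over WT labelled 1 week was 0.175 against 2.66 in DKO over WT. Mean Dars2 in WT labelled fl/fl over WT labelled fl/wt was 0.97 as labelled and 1.09 with the ages exchanged, which argues against lower expression from the floxed allele only if the genotype labels of single libraries hold. The series title gives all WT as fl/fl while 4 of 8 are labelled fl/wt, so this explanation stays open. A chromosome 1 segment that differs between the lines was neither supported nor excluded. Near Dars2, 14.5% of 76 genes within 5 Mb had an unadjusted p under 0.05 labelled 1 week and 12.5% of 80 labelled 2 weeks, against 11.4% and 12.6% of all genes. An effect of Chop on Dars2, or Cre activity in animals labelled without it, may also remain and was not tested.

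Genes near Ddit3 lay on the same side of WT in Chop KO at both ages more often than genes elsewhere. Of 123 genes within 10 Mb, 8 (6.5%) had an unadjusted p under 0.05 and the same sign at both ages, against 148 of 15897 elsewhere (0.931%; Fisher's exact test, two-sided, p = 2.7e-05). The 20 Mb bin of Ddit3 ranked highest of 137 bins at 7.14% against 5.97% for the next. The 8 genes were Dtx3, which was higher, and Timeless, Stat2, Rnf41, Erbb3, Wibg, Tmem198b and Dnajc14, which were lower, and were named after their values were seen. Differences spread evenly over the genome would give equal shares, but the share of 0.931% elsewhere belongs to the same comparison and is no separate test. A chromosome 10 segment carried along with the knockout allele is a candidate explanation. Regulation of its neighbours by Chop or by the changed locus stays open and was not tested.

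Dixon's test set 1 library apart from the other 3 of its group in 6 of 64 groups examined. Chance alone marks about 1 in 20. The mitochondrial share was 26.4% in Dars2 KO labelled 1 week replicate 2. Ddit3 was 17.1 CPM and Atf5 95.3 CPM in DKO labelled 1 week replicate 4. Gdf15 was 34.2 CPM in Dars2 KO labelled 1 week replicate 4. Asns was 3.26 CPM in Chop KO labelled 1 week replicate 3 and 12.2 CPM in Dars2 KO labelled 2 weeks replicate 1.

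Effects that differed between groups by the test of the difference itself were the interaction of both losses labelled 1 week (5735 genes), the effect of losing Dars2 between ages (34 genes) and the effect of losing Chop on top of it between ages (6377 genes). By gene, the effect of losing Dars2 differed on the log2 scale, 2 weeks label minus 1 week label, by -4.31 for Gdf15, -4.15 for Mthfd2, -3.94 for Soat2 and -3.52 for Asns. The effect of losing Chop in Dars2 KO was 9.20 higher for Htr3a, 7.05 for Lrat, 5.50 for Clec18a and 5.36 for Aldh3b3, and -6.14 for Dhrs9, -6.09 for Sprr1a, -5.95 for Crlf1 and -5.91 for Ankrd2. The Htr3a value rests on a group of 0 counts and the Aldh3b3 value on a group of 2, DKO labelled 1 week in both, and neither is a bound.

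Splits of the libraries tested whether other divisions of the same animals give as many genes, with the groups compared fitted alone. The real split alone gave as many genes for Dars2 KO against WT labelled 1 week (149 genes, 1 of 35, highest other 4). It did so too for DKO against Dars2 KO labelled 1 week (7105, 1 of 35, highest other 0). The same held for Chop KO against WT labelled 1 week (124; 1 of 35; 9) and DKO against Chop KO labelled 1 week (7821; 1 of 35; 0). It also held, by a smaller margin, for DKO against Dars2 KO labelled 2 weeks (14, 1 of 35, 9) and Chop KO against WT labelled 2 weeks (21, 1 of 35, 11). The fit of all 4 genotypes called 34 genes and 1 gene in these comparisons, and both fits shared 9 genes and 1 gene. The smallest share that 35 splits can give is 1 of 35, and it was not adjusted over the comparisons. Taken alone it does not exclude chance. Other splits gave as many genes for DKO against Chop KO labelled 2 weeks (2 genes, 3 of 35, highest other 6). They did so for the interaction labelled 2 weeks (0 genes, 50 of 50, highest other 5), so chance was not excluded for these. For Dars2 KO against WT labelled 2 weeks chance was not excluded either (1 gene; 4 of 35), and the split of WT replicates 1 to 3 with Dars2 KO replicate 3 against the rest called 3386 genes, which points to a structure of the samples. Few splits gave as many genes for the interaction labelled 1 week (5735 genes, 1 of 50) and the age difference of losing Dars2 (43, 2 of 50). The same held for the age difference of losing Chop on top of it (5438, 1 of 50). These splits exchanged Chop status within each state of Dars2, or age within each genotype. They mixed libraries that differ by Chop status or age itself, so they cannot decide whether chance gave a difference of effects. For these comparisons, in the order given, the highest other splits called 5644, 6725 and 4433 genes. Each of these exchanges most libraries of a group that differs strongly from the others, so it carries part of a real difference between groups and points to a structure of the samples.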

How the results depend on the processing

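Sex read from Xist and Y-linked transcripts was chosen as a covariate after the data were seen; every other setting was planned. Counts for DKO against Dars2 KO, DKO against Chop KO and the interaction labelled 1 week, for the age difference of losing Chop in Dars2 KO and for WT between ages stayed within 1.5 times under every setting run. The following did not, and the cause was not tested. DESeq2 gave 292 genes for Dars2 KO against WT, and 290 for Chop KO against WT labelled 1 week. Labelled 2 weeks it gave 6 for Dars2 KO against WT, 349 for DKO against Dars2 KO, 297 for Chop KO against WT, 187 for DKO against Chop KO and 2 for the interaction, with 69 for the age difference of losing Dars2. Limma-voom gave 42 for Chop KO against WT labelled 1 week, 0 for DKO against Chop KO labelled 2 weeks and 13 for that age difference. Without the low-count filter these became 43, 4 and 21, with 54 for DKO against Dars2 KO and 18 for Chop KO against WT labelled 2 weeks. The filter of 1 CPM in 4 libraries gave 5 for DKO against Chop KO labelled 2 weeks, and the labelled sex as covariate 0. Sex from the transcripts gave 10 for Chop KO against WT labelled 1 week, and 18 for DKO against Dars2 KO and 0 for DKO against Chop KO labelled 2 weeks. The replicate block, for numbers that do not pair the libraries, gave 6 for Chop KO against WT labelled 1 week, and labelled 2 weeks 1 for DKO against Chop KO and 1 for the interaction. A fit of the compared groups alone gave 124 for Chop KO against WT labelled 1 week, and labelled 2 weeks 1 for Dars2 KO against WT, 14 for DKO against Dars2 KO (1 higher and 13 lower, against 18 and 16), 21 for Chop KO against WT (7 higher and 14 lower) and 2 for DKO against Chop KO (0 higher and 2 lower, against 8 and 0).

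Leaving out each library in turn gave these ranges of genes: Dars2 KO against WT 80 to 168 labelled 1 week and 0 to 7 labelled 2 weeks, and DKO against Dars2 KO 7354 to 8411 and 0 to 86. They were for Chop KO against WT 1 to 63 and 1 to 15, DKO against Chop KO 8096 to 8922 and 0 to 27, and for the interaction 5044 to 6152 and 0 to 0. The age differences ranged from 14 to 49 for losing Dars2 and from 5482 to 6703 for losing Chop on top of it, and WT between ages from 7588 to 7839. Over the 184 pairs of a named gene and a comparison, 3310 values under other settings gave the same call in 3007, a lost call in 296, a gained call in 7 and a reversed sign in 0. RLE factors in place of TMM moved the median change of all genes by at most 0.043 on the log2 scale in any comparison.

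Of 203 list calls by camera, the estimated correlation kept 4, all in the same direction, and ended 199; RLE factors ended 0, the labelled sex 5 and the replicate block 2. With the estimated correlation 2 lists stayed called for Dars2 KO against WT labelled 1 week, 1 for DKO against Chop KO labelled 1 week and 1 for the age difference of losing Dars2, and 0 for each other comparison. At an adjusted p under 0.01, overlaps of called genes were 58 higher and 9 lower for loss of Dars2 with and without Chop labelled 1 week, and 1 and 0 for loss of Chop with and without Dars2 labelled 1 week. They were 0 lower for the same labelled 2 weeks, 0 for DKO against Chop KO at both ages and 0 and 0 for DKO against Dars2 KO at both ages, where fewer genes pass by construction. Counts of 0 over a group limit what can be said of the size of change for Htr3a, Vmn2r3 and Cntnap3; how depth limits other genes was not tested.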

Other observations

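Of the tests in this part, those of the split of libraries were chosen after the split was seen, and those against Chop KO after the share for WT was seen. WT hearts differed between the labelled ages in many genes. Tnni1 was 8.01 ± 0.58 higher in WT labelled 2 weeks than in WT labelled 1 week (adjusted p = 5.39e-11 in edgeR). The division genes Hmmr and Cdc25c rose by 4.63 ± 0.44 and 4.62 ± 0.40. Xkr5 rose by 4.86 ± 0.43. Cyp2e1, an enzyme of ethanol and drug oxidation, fell by 5.73 ± 0.96, as did Prss55 (-5.63 ± 0.65), Tmem52 (-5.51 ± 0.57) and the chemokine gene Cxcl14 (-4.84 ± 0.43). In edgeR 8411 of 17561 genes passed, 4131 higher and 4280 lower. In splits of the 8 libraries the real one alone of 35 gave as many (8371 genes with these groups fitted alone, highest other 6), the smallest share that 35 splits can give. Of 24 cell cycle genes, 24 rose (24 adjusted over the list alone), for example Aurka (3.47 ± 0.26), Bub1b (3.30 ± 0.27) and Rrm2 (3.59 ± 0.30; camera adjusted p = 1.79e-15, adjusted p = 0.182 with an estimated correlation). Of 18 fibroblast and matrix markers, 14 rose and 2 fell (14 and 2 adjusted over the list alone), with Postn at 2.34 ± 0.20 (camera adjusted p = 0.000227, adjusted p = 0.417 with an estimated correlation).

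Most complex I subunits, fatty acid oxidation genes and mitochondrial mRNAs were lower in WT labelled 2 weeks. Of 36 complex I subunits, 36 fell (36 adjusted over the list alone), for example Ndufa10 (-0.85 ± 0.06; camera adjusted p = 2.19e-23, adjusted p = 0.158 with an estimated correlation). Of 27 fatty acid oxidation genes, 1 rose and 22 fell (1 and 22 adjusted over the list alone), for example Hadh (-1.02 ± 0.07; camera adjusted p = 4.5e-10, adjusted p = 0.205 with an estimated correlation). Of 13 mitochondrial mRNAs, 12 fell (12 adjusted over the list alone), with mt-Nd2 at -1.51 ± 0.12 (camera adjusted p = 1.27e-07, adjusted p = 0.158 with an estimated correlation). The adult troponin I gene Tnni3 stood at -0.80 ± 0.08 and Rpl3l, the muscle form of a ribosomal protein, at -3.08 ± 0.29. Of 23 interferon-stimulated genes, 18 fell (18 adjusted over the list alone), for example Oas2 (-2.20 ± 0.28; camera adjusted p = 2.02e-05, adjusted p = 0.285 with an estimated correlation). Of 16 macrophage and myeloid markers, 11 fell (11 adjusted over the list alone), for example C1qa (-1.28 ± 0.17; camera adjusted p = 0.00125, adjusted p = 0.408 with an estimated correlation). Age and project cannot be told apart here.

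A hypothesis on the split that called 3386 genes at the 2 weeks label was tested with a prediction written before that prediction was checked. WT replicates 1 to 3 and Dars2 KO replicate 3 may be hearts at another stage of maturation than the other 4 libraries. Of 2225 genes that the split called and that also differed between WT labelled 2 weeks and WT labelled 1 week, 1950 (87.6%) lay in these 4 libraries on the side of WT labelled 1 week, though the split and the age comparison share WT libraries. Against the age difference of Chop KO, which shares no library with the split, 2221 of 2510 genes (88.5%) lay on the side of the 1 week label. Over all 9583 genes that differed with age in Chop KO, called in the split or not, the split put 67.9% on one side, and 2 of 35 splits gave as high a share (median of the others 58.1%, highest 68.1%). Tnni1, chosen after its values were seen, was at 390 to 618 CPM in them and at 676 to 1160 CPM in the others of the comparison. It was not tested, since the libraries were picked by their values, and lay at 0.498 to 7.44 CPM labelled 1 week. The split was found in the same data and another split gave as high a share, so this stays a hypothesis.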
